A study of Columba livia with 19 samples.

How the data were processed

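Messenger RNA was measured in the collar of regenerating flight feathers from 19 domestic rock pigeons (Columba livia). Per the labels' protocols, secondary flight feathers were plucked and allowed to regrow for 9 to 10 days. The proximal 4 to 5 mm of each regrowing pigmented feather was then dissected, the dermal pulp was discarded, and polyadenylated RNA of the collar was sequenced on Illumina libraries. The bird is the replicate. Per the labels, batch 1 (sequenced in 2017) held 3 recessive red birds homozygous for the e1 allele and 4 wild-type birds. Batch 2 (collected in 2020) held 3 recessive red e1 homozygotes, 3 recessive red e2 homozygotes, 5 wild-type birds and 1 wild-type carrier of e1. The labels give no sex for any bird.

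The authors deposited 1 table of raw counts per gene, with 1 column of whole-number counts for each of the 19 birds and 15392 rows, of which 207 were 0 in every bird. Beside the counts, the authors deposited the log2 fold changes, their standard errors, test scores and p-values of a DESeq2 comparison, per the file headers. DESeq2 is listed without a version in the submitters' processing notes. The aligner, the counting program and whether counting used strand are not given in the sources used here. The gene identifiers are headed Cliv2.1 in the file header. They were looked up in a table of 22830 pigeon genes of the assembly bColLiv1.pat.W.v2, and 0 identifiers matched. The files used here do not pair the identifiers with gene names, so genes are given by identifier and no position is printed. For the same reason SOX10 and other pigment genes were not analysed here. The 21 gene lists fixed beforehand, among them pigment pathways and a list of chicken Z chromosome genes planned as a sex covariate, could not be tested, as 0 of their members matched.

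Total counts per bird ranged from 13559606 to 23168538. Genes were kept by filterByExpr of edgeR (version 4.0.16, in R 4.3.3), libraries were scaled by TMM, and genes were tested with edgeR's quasi-likelihood test. P-values were adjusted by the method of Benjamini and Hochberg, and a gene was called changed at an adjusted p under 0.05 with no minimum fold. The comparison of phenotypes in all birds had the batch as a term and counted the carrier as wild type. The phenotypes were also compared within each batch, and an interaction of batch and phenotype was tested in a single fit. The alleles were compared within batch 2 in a fit with a coefficient for each allele and one for the carrier. All log2 fold changes are from these fits, and the standard error of a fold change was its size divided by the square root of the F statistic. CPM values printed per group are counts scaled to the TMM-scaled library size, as mean ± SD over birds. Counting intervals are exact Poisson intervals at 95% and cover counting error only.

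The rule fixed beforehand would have named the 12 genes with the largest change in each direction that had a gene symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same sign in both batches. With no symbols the rule was applied without that requirement, and the 2 leading genes in each direction are named. A further 4 genes, the 3 called between the alleles and the 1 called higher in batch 1, were named after their values were seen, because those counts were 5 or fewer.

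The test was tried on counts simulated from the means, dispersions and library sizes of the real genes, with 100 genes changed 2-fold and 100 changed 4-fold. For all birds (12839 genes) it recovered 89% of the 2-fold and 98% of the 4-fold changes, and 6.03% of its calls were false. For batch 1 (12693 genes) the recovered shares were 65% and 91%, for batch 2 (12459 genes) 83% and 95%, and for e2 against e1 (13269 genes) 46% and 92%. DESeq2 (version 1.42.0) on the same simulated counts recovered 91% and 99% for all birds, and 14.4% of its calls were false. The counts were drawn once per comparison from edgeR's own dispersions, with no batch effect and no correlation between genes. These settings may favour edgeR.

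Alternatives set before the data were examined were DESeq2 size factors or upper-quartile scaling in the edgeR fit, no filter or a stricter filter on low counts, the DESeq2 Wald test, a minimum absolute log2 fold change of 1, and leaving out each bird in turn. For all birds they also included no batch term, leaving out the carrier or the e2 birds, 1 surrogate variable from sva (version 3.50.0), and the bird number as a block. Covariance of the 2 allele comparisons, which share their wild-type birds, was set beside 40 simulated data sets with no change in either allele.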

Results

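The series compared growing feathers of wild-type pigeons, which make black to brown eumelanin, with those of recessive red pigeons, which make red to yellow pheomelanin. Recessive red birds are homozygous for the e1 or the e2 allele, which are mutations at SOX10, a gene for a transcription factor of the neural crest lineage from which melanocytes arise. RNA of the feather collar, the ring of growing epidermis that holds the melanocytes, was counted in 9 recessive red and 10 wild-type birds collected in 2 batches. Total counts ranged from 13559606 to 23168538 per bird. They averaged 17646046 ± 2892754 (SD, n = 9) in recessive red and 17522352 ± 2461827 (SD, n = 10) in wild type, a difference that did not exceed the spread between birds (permutation test within batches, 2-sided, p = 0.904, adjusted p = 0.904 over 4 library measures). The first principal component of the log2 CPM values held 24.8% of the variance and parted the batches, with batch 1 birds between -40.7 and -24.0 and batch 2 birds between -12.9 and 39.0. The second component held 16.6% and parted the phenotypes.

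**Figure D1:**
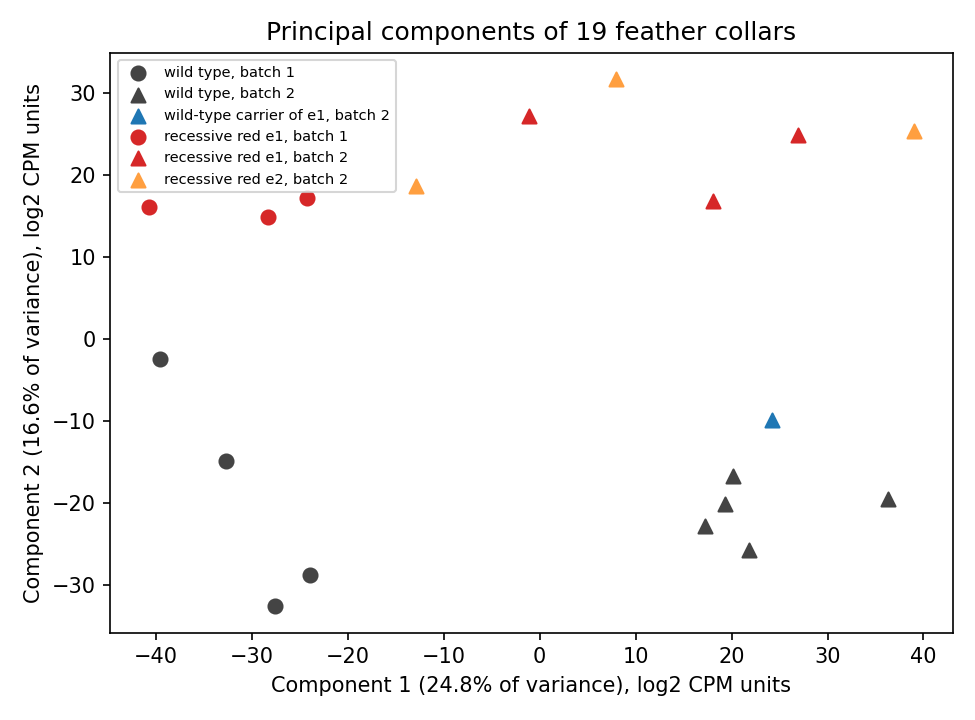
Principal components of log2 CPM over the 12839 tested genes, 1 point per bird, with the share of variance on each axis, colours for the genotype groups, circles for batch 1 and triangles for batch 2. Recessive red birds lie above wild-type birds on the second component, where wild-type bird 2 at -2.41 and the carrier at -9.84 are the wild-type birds closest to the recessive red ones.

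The first question was which transcripts of the collar differ between recessive red and wild-type birds. In all 19 birds, 331 genes were lower and 211 were higher in recessive red. In all birds, 45 lower genes fell at least 4-fold and 9 at least 16-fold, against 19 and 2 of the higher genes. In batch 2 alone 23 lower and 29 higher genes changed at least 4-fold, and in batch 1 alone 34 and 1. The median log2 fold change was -0.77 over the lower and 0.85 over the higher genes. In 48 lower genes every recessive red bird was below every wild-type bird, and in 6 higher genes every recessive red bird was above. Chance gives such a separation, in either direction, in 0.00217% of groupings of 9 and 10 birds for a single gene fixed beforehand, when batches are ignored. These genes were instead chosen for their difference between the same birds. Together the lower genes took 2.85 ± 0.436% of the counts in wild type of batch 1 (SD, n = 4) and 2.97 ± 0.629% in batch 2 (SD, n = 6). In recessive red they took 1.16 ± 0.0380% (SD, n = 3) and 1.38 ± 0.0688% (SD, n = 6). These genes were chosen for that difference in the same birds.

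The gene A306_00007909 was lost almost entirely from recessive red collars. It stood at 6650 ± 1223 CPM in wild type of batch 1 (SD, n = 4) and at 5668 ± 1918 CPM in wild type of batch 2 (SD, n = 6). In recessive red it stood at 1.51 ± 0.578 CPM (SD, n = 3) and 7.82 ± 7.51 CPM (SD, n = 6). Its log2 fold change was -10.25 ± 0.59 (SE; edgeR quasi-likelihood test, adjusted p = 6.56e-10), and it was lower in each of the 9 recessive red birds, which held 17 to 445 counts, than in any wild-type bird, which held 46653 to 149236. The gene A306_00015279 had 4 counts over the 9 recessive red birds and 872 over the 10 wild-type birds. Scaled to library size, that is a ratio of 199 with a 95% counting interval of 77.6 to 734. Its fitted log2 fold change of -7.31 ± 0.57 (SE; edgeR, adjusted p = 7.97e-08) depends on the prior count. All 3 e2 birds were at 0 for A306_00015279, which with a floor of 3 counts over the group puts them at least 105-fold lower than the 5 homozygous wild-type birds of batch 2.

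The 2 higher genes that lead under the naming rule, which asks for a mean log2 CPM of at least 1 and the same sign in both batches, were rare in wild type. A306_00008834 rose with a log2 fold change of 3.84 ± 0.42 (SE; edgeR, adjusted p = 9.53e-06). It stood at 0.684 ± 0.503 CPM in wild type (SD, n = 4) and 5.43 ± 4.30 CPM in recessive red (SD, n = 3) of batch 1, and at 0.328 ± 0.218 CPM (SD, n = 6) and 7.01 ± 2.40 CPM (SD, n = 6) in batch 2. A306_00009048 rose with a log2 fold change of 3.69 ± 0.57 (SE; edgeR, adjusted p = 4.39e-04). In batch 1 it stood at 0.810 ± 0.890 CPM in wild type (SD, n = 4) and 5.94 ± 3.12 CPM in recessive red (SD, n = 3). In batch 2 its recessive red birds ranged from 2.24 to 24.9 CPM and its wild-type birds from 0.117 to 0.969 CPM. In batch 1 alone neither gene was called (edgeR, adjusted p = 0.160 for A306_00008834 and 0.161 for A306_00009048). The total of 542 changed genes was reached among 12839 tested with edgeR's quasi-likelihood test. It became 855 without wild-type bird 2, 872 with DESeq2, 336 with no batch term and 220 with a minimum absolute log2 fold change of 1.

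**Figure D2:**
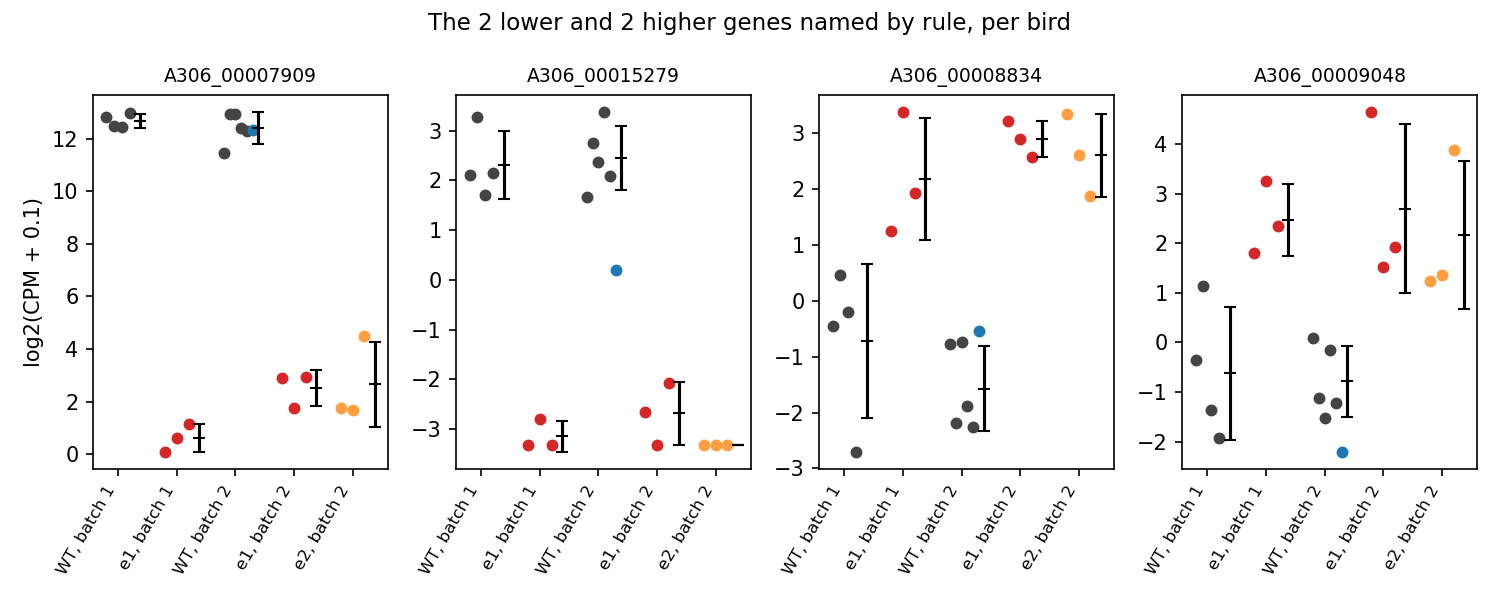
Log2 of CPM plus 0.1 in each bird for the 2 lower and the 2 higher genes that lead among called genes with a mean log2 CPM of at least 1 and the same sign in both batches, by phenotype, allele and batch, with grey points for homozygous wild type, blue for the carrier, red for e1 and orange for e2, and black bars for mean and SD of the homozygous groups. For A306_00007909 and A306_00015279 each recessive red bird lies below each wild-type bird, and the carrier lies at 5091 and 1.05 CPM.

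The second question was whether the difference was the same in the birds of 2017 and the birds of 2020. In batch 1, 58 genes were lower and 1 was higher in recessive red (edgeR, 12693 genes tested), while in batch 2, 182 were lower and 299 higher (edgeR, 12459 genes tested). Most genes lower in batch 1 recurred: 38 of the 58 were also called lower in batch 2, against 0.853 expected for independent lists (Fisher's exact test across genes, p = 5.63e-57). Of the 58, 55 had the same sign. From the side of batch 2, the shared genes were 38 of 182. The 1 gene called higher in batch 1, A306_00007803, had a log2 fold change of 3.53 ± 0.51 (SE; edgeR, adjusted p = 0.0168) in batch 1 and 3.49 ± 0.44 (SE; edgeR, adjusted p = 5.38e-04) in batch 2. Over all genes tested in both batches, 7000 of 12376 (56.6%) had the same sign. The genes called higher in batch 2 had a median log2 fold change of 0.85 there and 0.19 in batch 1, where 224 of 298 kept the sign. The genes called lower in batch 2 had medians of -0.84 in batch 2 and -0.67 in batch 1, where 164 of 182 kept the sign. Choosing genes by their batch 2 values enlarges the batch 2 medians, so these medians do not compare the size of change between batches. When genes were chosen in a part of batch 2, lower genes had a median of -2.17 in the held-out part and -3.21 in batch 1. Higher genes chosen in this way had 1.48 and 0.79. Across the 12376 genes tested in both batches, the log2 fold changes had a Pearson r of 0.534 and a Spearman rho of 0.226. Genes are not independent replicates, and most of the tested genes were not called in either batch.

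No single gene passed a test of the difference between the batches: 0 of 13027 genes had an interaction of batch and phenotype by edgeR, and DESeq2 called 5. By edgeR 908 of the 13027 genes had an unadjusted p under 0.05, where a share of 0.05 would pass by chance if no gene differed. The interaction count was 79 without recessive red bird 3. The count of 59 genes in batch 1 became 28 without recessive red bird 1, 29 without bird 4 and 148 without bird 3. It became 238 with DESeq2. The count of 481 in batch 2 fell to 266 without wild-type bird 00, 268 without bird 20, 306 without bird 24, 304 without the carrier and 311 without recessive red bird 14, and was 1029 with DESeq2 and 204 with a minimum absolute log2 fold change of 1.

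**Figure D3:**
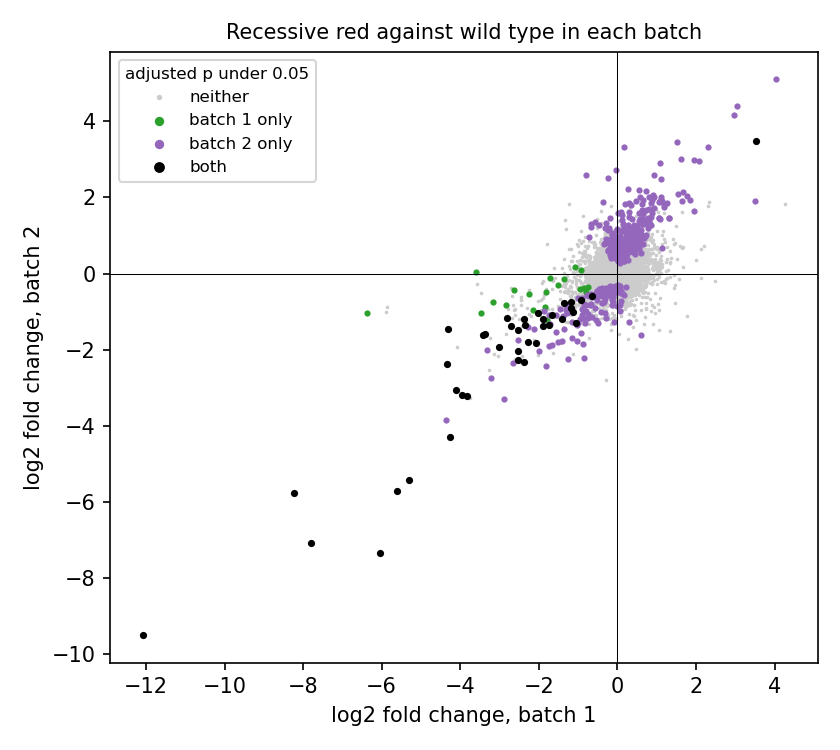
Log2 fold change of recessive red against wild type in batch 1 (x axis) and batch 2 (y axis), 1 point per gene tested in both, coloured by the batch in which its adjusted p was under 0.05. The 38 shared lower genes extend along the diagonal to A306_00007909 at -12.08 and -9.49. The genes called higher in batch 2 have a median of 0.19 in batch 1. Among them A306_00008834 and A306_00009048, which were not called in batch 1, stand at 3.04 and 2.97 there.

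The third question was whether the e1 and e2 alleles have the same effect, which only batch 2 can answer. Against the 5 homozygous wild-type birds, 67 genes were lower and 85 higher in e1, and 89 were lower and 139 higher in e2 (edgeR, 13269 genes tested). Both alleles shared 47 lower genes, where independent lists would share 0.449, and 54 higher genes, where independent lists would share 0.890. The log2 fold changes of the alleles had the same sign in 73.2% of all tested genes, with a Pearson r of 0.665 and a covariance of 0.223 across genes. Both comparisons use the same wild-type birds, and 40 simulations of unchanged birds against those controls gave a median of 62.3% same signs, a median r of 0.370 and a median covariance of 0.0393. The covariance was therefore 0.183 above that of unchanged groups. With the wild-type birds divided between the alleles, the median over 20 divisions was 66.8% same signs, an r of 0.495 and a covariance of 0.183, with 17.5 lower and 11 higher genes shared.

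Tested directly, e2 and e1 differed in 3 genes, 1 higher and 2 lower in e2. A306_00012780 stood at 24.4 ± 2.23 CPM in e2 (SD, n = 3), 9.86 ± 0.747 CPM in e1 (SD, n = 3) and 9.52 ± 1.02 CPM in wild type (SD, n = 5), with a log2 difference of 1.29 ± 0.16 (SE; edgeR, adjusted p = 0.0452). A306_00013822 stood at 47.4 ± 1.98, 96.5 ± 14.6 and 147 ± 16.2 CPM in the same groups, with a log2 difference of -1.04 ± 0.15 (SE; edgeR, adjusted p = 0.0453). A306_00009490 stood at 6.22 ± 1.30, 20.9 ± 1.60 and 48.6 ± 13.5 CPM, with a log2 difference of -1.76 ± 0.25 (SE; edgeR, adjusted p = 0.0453). The e1 birds of batch 1 (SD, n = 3), which did not enter this fit, stood at 57.1 ± 29.1 CPM for A306_00013822 and 7.55 ± 2.40 CPM for A306_00009490. Wild type of that batch stood at 143 and 31.8 CPM. In CPM both e1 values of batch 1 were nearer to e2 than to e1 of batch 2, but wild type also differed between the batches. Against wild type of the same batch, the log2 fold changes of A306_00013822 were -1.31 in e1 of batch 1, -0.59 in e1 of batch 2 and -1.63 in e2. For A306_00009490 they were -2.07, -1.21 and -2.97, so e1 of batch 1 lay between the alleles of batch 2 and not clearly nearer to e2. For A306_00012780 the e1 birds of batch 1 were at 9.08 ± 0.966 CPM, near the e1 level of batch 2. Within batch 2, each e2 bird lay below each e1 bird in A306_00013822 and A306_00009490, and above in A306_00012780. Chance gives such a separation in 10% of groupings of 3 and 3 for a single gene fixed beforehand. These 3 genes were instead chosen for their difference between the same birds. An unadjusted p under 0.05 was found for 800 of the 13269 tested genes, where a share of 0.05 would pass by chance if no gene differed. The count of 3 fell to 0 in a fit of the 6 recessive red birds alone, and to 0 without any 1 of e1 birds 11 and 12, e2 birds 5, 7 and 14 and wild-type birds 00, 20, 21 and 23. It was 1 without e1 bird 6, a gene other than these 3, 1 with upper-quartile scaling and 28 with DESeq2. With birds left out in turn the log2 differences stayed between 1.22 and 1.36 for A306_00012780, -1.15 and -0.95 for A306_00013822, and -1.85 and -1.60 for A306_00009490. For 125 of the 279 genes called in either allele the 95% interval of the difference lay within 1 log2 unit of 0. The median half-width of that interval, which is not adjusted for the number of genes, was 0.63 log2 units.

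**Figure D4:**
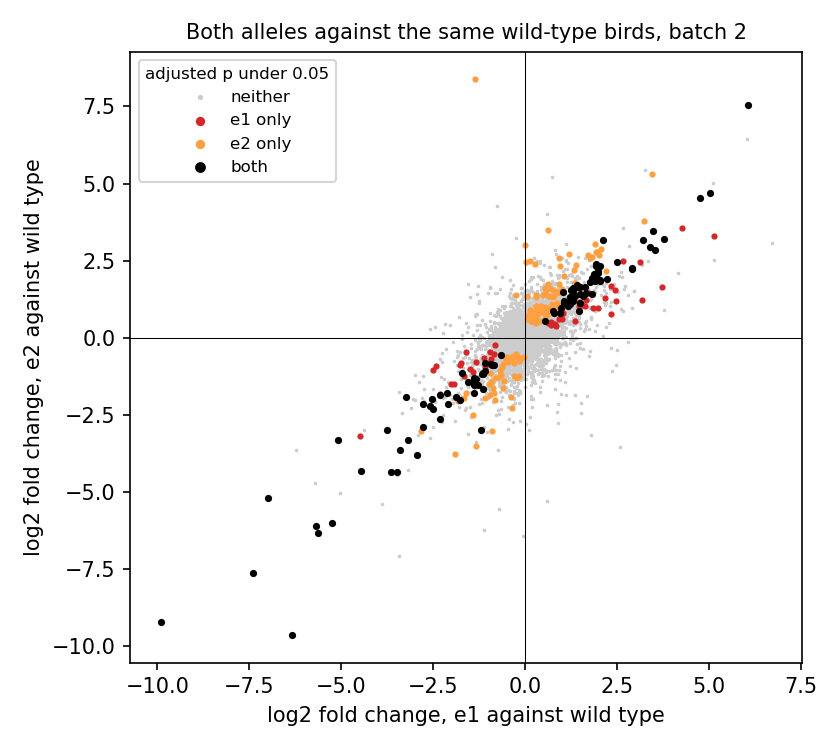
Log2 fold change of e1 (x axis) and e2 (y axis) against the same 5 wild-type birds of batch 2, 1 point per gene, coloured by the comparison in which its adjusted p was under 0.05. The 101 genes called in both lie along the diagonal in both directions.

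The e1 count of 152 became 73, 97 and 78 without e1 birds 6, 11 and 12, 90 and 100 without wild-type birds 20 and 23, and 355 with DESeq2. The e2 count of 228 became 95 without e2 bird 14, 138, 128 and 143 without wild-type birds 00, 20 and 23, and 690 with DESeq2.

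The last question was where the single carrier of e1 lies. The 58 genes lower in batch 1, whose choice did not involve the birds of batch 2, were summarised in each batch 2 bird as the median log2 CPM relative to the other homozygous wild-type birds. The score was -1.34 ± 0.23 (SD, n = 3) in e1 and -1.27 ± 0.25 (SD, n = 3) in e2. The alleles did not differ by more than the spread between birds (exact permutation test, 2-sided, p = 0.6, where 3 against 3 birds cannot go below 0.1). Homozygous wild-type birds averaged 0.01 ± 0.39 (SD, n = 5) and ranged from -0.44 to 0.31. The carrier had a score of -0.36, above the highest recessive red bird at -0.99 and close to the lowest wild-type birds, 00 and 24. Each homozygous wild-type bird was left out of its own reference, which widens its score, while the carrier was scored against all 5. These scores therefore do not settle whether the carrier lies within the wild-type range. Of the 58 genes, 54 were below the wild-type mean in the carrier, 55 in bird 00 and 47 in bird 24. For A306_00007909 the carrier stood at 5091 CPM, within the wild-type range of 2824 to 7918 CPM. For A306_00015279 it stood at 1.05 CPM from 18 counts, below the lowest homozygous wild-type bird at 3.09 CPM. With 1 carrier there is no replicate and no test.

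**Figure D5:**
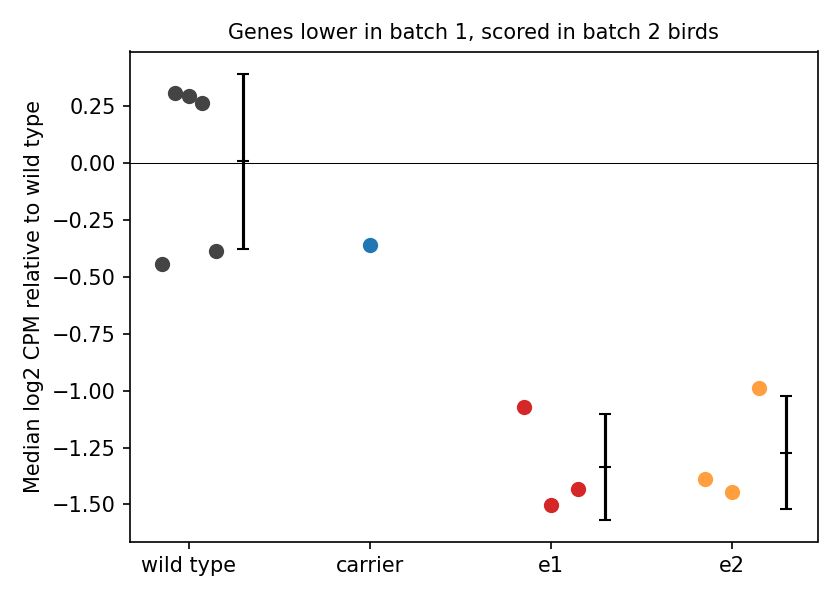
Median log2 CPM of the 58 genes lower in batch 1, relative to homozygous wild type, for each bird of batch 2 (points) with mean and SD (bars) of each group of more than 1 bird. The 6 recessive red birds lie between -1.50 and -0.99, and the carrier lies at -0.36. The lowest wild-type bird is at -0.44, on a reference that leaves that bird out and so widens its score.

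In the authors' deposited table, 872 genes had an adjusted p under 0.05, of which 474 were lower and 398 higher, among 14283 with an adjusted p. The table does not state its model. A DESeq2 fit of all birds with a batch term differed from the log2 fold changes of the authors' deposited table by at most 4.15e-04 over 15185 genes and also called 872 genes, while a fit without a batch term differed by up to 4.19. All 542 genes called by edgeR were among the 872 calls of the authors' deposited table, with 0 of opposite sign.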

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

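The tests of the e2 birds of batch 2, of the spread among wild-type birds, of the gap in batch 2 and of the splits for the interaction were chosen only after the result was seen.

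The direct test between the alleles singled out the 3 genes that differed between e2 and e1, with log2 differences of 1.29 for A306_00012780, -1.04 for A306_00013822 and -1.76 for A306_00009490. Each was measured by the difference itself (edgeR, adjusted p = 0.0452, 0.0453 and 0.0453). The 6 recessive red birds can be split 3 against 3 in only 10 ways, so a share under 0.05 cannot be reached. 2 of the 10 splits gave 3 or more genes, and the highest other split, birds 5, 6 and 14 against birds 7, 11 and 12, gave 269. A split with so many genes points to a structure among the recessive red birds that follows neither allele. It goes with properties of the libraries: birds 5, 6 and 14 had 14325 to 14385 detected genes and 17271989 to 19299570 counts, and birds 7, 11 and 12 had 14157 to 14186 genes and 13559606 to 15170832 counts. On the first principal component the former lay between -12.9 and 8.0 and the latter between 18.0 and 39.0. What links these was not tested. Over 41 checks of single birds within groups of 4 to 6 birds, 0 birds stood apart from the others. The checks covered library measures, the named genes and the score of the genes lower in batch 1. They left out the carrier and the recessive red birds of batch 1. Single birds still moved the counts: batch 1 gave 148 genes without recessive red bird 3, and all birds gave 855 without wild-type bird 2.

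Other splits of the same birds were counted for the remaining results. For all birds, 1 of 100 splits within batches, the real one, gave as many as 542 genes, and the highest other gave 90, so no other split counted reached it. The same holds for batch 2, with 1 of 100 splits and 3 genes as the highest other beside 481, for e1 with 1 of 56 splits and 0 as the highest other beside 152, and for e2 with 1 of 56 splits and 106 as the highest other beside 228. The other splits mix the phenotypes, so the phenotype difference adds to the spread within their groups and lowers their counts. The 106 genes came from setting e2 bird 7 and wild-type birds 00 and 23 apart, birds that also group together in the pattern described next. For batch 1 the splits do not tell the phenotypes from chance, as 2 of 35 gave at least 59 genes and the highest other gave 145. The birds of batch 2, which did not enter the choice of the 58 lower genes, argue against chance as the source of these genes as a set. Of these genes 38 were called lower again, against 0.853 expected, 55 kept their sign, and their score was -1.30 ± 0.22 (SD, n = 6) in recessive red and 0.01 ± 0.39 (SD, n = 5) in homozygous wild type of batch 2. For the interaction the splits decide nothing: with a real count of 0, all 100 splits reach it by construction, and the highest other gave 131.

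The pattern behind the 145 genes is a grouping of birds across the phenotypes. The split set recessive red bird 3 and wild-type birds 3 and 4 against the other 4 birds of batch 1, and 144 of its genes were lower in the 3 birds, with a median log2 fold change of -0.94 and quartiles of -1.02 and -0.86. In the birds of batch 2, which did not enter the choice, the median of the 144 genes left a gap of 0.659 log2 units between 4 birds (recessive red 6 and 7, wild type 00 and 23) and the other 8, where random lists of like expression gave gaps of at most 0.0587. Each side of that gap in batch 2 held birds of both phenotypes. One explanation that stays open is a difference in sex, with 1 against 2 copies of the Z chromosome, which may underlie these genes. Birds largely lack dosage compensation of that chromosome, and the genes lie next to each other in the table in 29 pairs, where 10000 shuffles gave at most 7. As the labels give no sex and the identifiers no chromosome, this remains a hypothesis, and a difference in copy number of another region is not excluded.

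Lower genes made up 98.3% of the calls in batch 1 and 37.8% in batch 2. Fewer birds in batch 1 do not account for it: 60 subsets of batch 2 with 3 recessive red and 4 wild-type birds gave a median of 36.6% lower genes, and 0 subsets reached the share of batch 1. Nor does the scaling, as batch 2 reached at most 38.7% lower genes under 3 scalings, nor the e2 birds, as the e1 birds of batch 2 gave 44.1%. A smaller rise in batch 1 is consistent with the values: genes called higher in a part of batch 2 had a median log2 fold change of 1.48 in the held-out part and 0.79 in batch 1, with a median difference of -0.77, and the value was smaller in batch 1 for all 38 lists. The 38 lists came from overlapping divisions of the same batch 2 birds and were all set beside the same fit of batch 1, so they are not independent. Batch 2 also held e2 birds, which batch 1 did not, and their part in this difference of size was not tested. Genes called lower fell further in batch 1 (median -3.21) than in the held-out part (-2.17). What parts the batches (year, birds, library preparation) cannot be told apart with 2 batches.

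The carrier lay low on the genes lower in batch 1, at -0.36 log2 units. In that bird 10000 random lists of like expression had a central range of -0.04 to 0.07, so its scaled values were not low on genes in general. The scaling itself places the typical gene of each library near 0, so these lists cannot exclude a property of the library. A score at or above the lowest homozygous wild-type bird was taken as the sign of ordinary spread among wild-type birds only after the result was seen. The carrier's score lay 0.0856 above that bird. That bird was left out of its own reference, which widens its score, while the carrier was scored against all of them. The comparison therefore cannot decide on ordinary spread. Wild-type birds 00 and 24 had scores of -0.44 and -0.38. An effect of 1 copy of e1 stays open and untested with 1 carrier.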

How the results depend on the processing

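The covariate of the genes that part the birds, and leaving out birds for the correlation of batches, were chosen after seeing the data. The 7 counts stayed within 1.5 times their value under DESeq2 size factors, no filter and the stricter filter, and all but the e2 against e1 count (1 in place of 3) under upper-quartile scaling. The DESeq2 Wald test gave more genes in each comparison: 872 in all birds, 238 in batch 1, 1029 in batch 2, 5 for the interaction, 355 for e1, 690 for e2 and 28 for e2 against e1. On simulated counts for all birds, drawn from edgeR's own dispersions, 14.4% of DESeq2 calls were false, against 6.03% with edgeR. For batch 1 DESeq2 recovered 82% of the 2-fold changes against 65%, with 17.0% against 4.29% of calls false. For e2 against e1 it recovered 67% against 46%, with 13.2% against 3.50% false. For batch 2 DESeq2 recovered 86% against 83% of the 2-fold changes, with 19.4% against 4.81% of calls false. DESeq2 thus recovered more of the simulated changes, with a larger share of false calls. The simulations do not tell which further DESeq2 calls on the real counts are false. By construction, a minimum absolute log2 fold change of 1 lowered the counts to 220 in all birds and 204 in batch 2. The count in all birds was 336 with no batch term, and the cause was not tested. Batch 2 without the carrier, which has fewer birds, gave 304. The e2 against e1 count was 0 in the 6 recessive red birds alone, with fewer birds to estimate the spread, and 0 with the covariate, where the 3 log2 differences stood at 1.29, -1.04 and -1.76 with an adjusted p of 0.0872 each. With that covariate the other counts were 531 in all birds (495 genes shared with the 542), 82 in batch 1, 502 in batch 2, 0 for the interaction, 125 for e1 and 226 for e2. Leaving out each bird in turn gave 383 to 855 genes in all birds, 28 to 148 in batch 1, 266 to 561 in batch 2, 0 to 79 for the interaction, 73 to 177 for e1, 95 to 304 for e2 and 0 to 3 for e2 against e1. The correlation of batches was 0.882 over genes called in batch 1 and 0.883 over those called in batch 2, as both sets were chosen for large changes. Over all genes tested in both batches, where it was 0.534, it ranged from 0.394 to 0.578 when birds were left out. The 4 leading genes and A306_00007803 kept their direction and their call in all 30 other settings. The 3 genes between the alleles kept their direction in 19 settings, but passed the threshold in 7 (A306_00012780), 5 (A306_00013822) and 6 (A306_00009490), with adjusted p up to 0.322, 0.482 and 0.322. Bird numbers 1, 3 and 4 occur in both phenotypes of batch 1, but deviations of same-numbered birds had correlations of -0.193, -0.0813 and -0.126. No bird correlated best with its own number. The values thus gave no sign of a pairing by number, but 3 correlations cannot exclude a shared block. With the number as a replicate block the counts were 718 in all birds and 39 in batch 1. The gene lists, SOX10 and the Z chromosome covariate were not run, as 0 identifiers matched a gene name. With 13559606 to 23168538 counts per bird, depth limits mainly genes near 0 in a phenotype: 17 lower genes had at most 10 counts in every recessive red bird and 9 higher genes had at most 10 in every wild-type bird.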

Other observations

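Genes lower in recessive red lay side by side in the table of identifiers more often than shuffled positions gave, though most of them did not lie next to another. The 331 lower genes formed 23 adjacent pairs, where shuffled positions gave a median of 7 and at most 20 in 10000 shuffles, so a random placement is excluded. The 211 higher genes formed 8 adjacent pairs, where shuffles gave a median of 3, at most 7 within their central 95% and at most 12 in all. Their pairs thus lay just above the central range but within what shuffling reached. The order of the identifiers is not stated to follow the genome. Neighbouring members of a gene family that share reads may contribute to such pairs, as may neighbours under common control, and the 23 pairs do not part these.

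Recessive red birds 3, 6 and 7 and wild-type birds 3, 4, 00 and 23 had median values from -0.89 to -0.38 over the 144 genes that part the birds, and the other 12 birds from 0.15 to 0.57 (log2 CPM relative to the mean of all birds). Both phenotypes are thus found on both sides, with 3 of 9 recessive red and 4 of 10 wild-type birds below the gap.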
